A study of Sus scrofa with 9 samples.

How the data were processed

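Gene expression was measured in the longissimus dorsi, the long muscle of the back, of 9 male finishing pigs with 1 array per pig. Per the labels, the pigs weighed about 95 kg at the start and were fed a lysine-deficient, a lysine-adequate or a lysine-excess diet for 5 weeks, with 3 pigs per diet. Per the labels' protocols, total RNA was extracted with TRIzol from frozen muscle, amplified to sense-strand cDNA and hybridised, after biotin labelling, to whole-transcript GeneChip arrays. The deposited values are the authors' processed values on a log scale, taken here as log2 because they run from 3.097 to 14.303. GCOS 1.2 and Partek are named in the submitters' processing notes without a role, and the background correction, summarization and normalization are not given in the sources used here. The log base is therefore inferred, and every fold change below rests on it. No value was missing, and the array medians lay between 5.01 and 5.21.

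The table holds 27558 probe sets. Gene symbols came from the platform annotation supplied with the values, updated through Entrez gene IDs: 13323 probe sets had 1 symbol, 357 had several and 13878 were unnamed here. The ID of 12968 of the probe sets with 1 symbol matched the pig gene table, which changed 7 symbols, and 12361 distinct genes resulted. The values of 1239 probe sets were identical to those of another probe set, so their genes are not measured independently. Control probe sets could not be told from the others in the tables used here, so all probe sets entered the tests, although the plan was to leave controls out. Probe sets with 1 symbol were also tested alone. No coordinates are given, because the genome build of the array was not stated.

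The deposited log2 values were used without further normalization. A linear model with 1 mean per diet was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 prior variance), and the comparisons were deficient against adequate, excess against adequate and deficient against excess, plus an F test for any difference among the diets. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all probe sets, and the threshold was an adjusted p of 0.05. Errors of differences are standard errors (SE) from this model, and SD is the spread among the 3 pigs of a group. The replicates were separate pigs, and 3 arrays per group limit the precision. The median SE of a log2 difference was 0.13. Signal over background was not tested, and the lowest group means of PHGDH, PSPH, CPEB2, MIR296, DGAT2 and LIPE lay below the median of all probe sets, 5.07, so their folds are not exact.

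Before the data were examined, 43 gene lists were fixed, covering muscle fibres, amino acid and protein metabolism, lipid metabolism, stress responses and markers of other cell types. The 42 lists with at least 5 measured genes were tested with limma's camera at the preset inter-gene correlation of 0.01, using for each gene its probe set with the highest mean. The 4 measured markers of the neuromuscular junction were too few. Each list was also tested with an estimated correlation and with fry, in 1 direction and in either direction (mixed), and its members were adjusted over the list alone. This last adjustment does not correct for the 42 lists or the 3 comparisons, so some passes over a list alone can arise by chance. Genes were named by a rule fixed in advance. In each comparison and direction, the rule took up to 10 genes past the threshold. Where fewer passed, it filled the places by the smallest unadjusted p among genes at or above the median level whose 3 pigs of one diet all lay beyond the 3 of the other. The rule added the 4 leading members of each list past the threshold and a set of key genes. Genes named outside the rule were chosen after their values were seen. They are ARG2 and, in the deficient against adequate comparison, AMD1, CEBPG and HSPD1, PHGDH and PSAT1 in the excess against adequate comparison, and HSPD1 and LIPE in the deficient against excess comparison.

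The fit was tested on simulated data with changes added to 100 probe sets at each of 2 sizes among the 27558 of the deficient against adequate comparison. It called 60 of 100 probe sets changed 2-fold and 86 of 100 changed 4-fold, with 10 false calls. The simulated noise was normal and independent between probe sets, without the correlations and array differences of the real data. These shares therefore do not give the power of the real comparisons. Camera was tested on 50 simulated datasets without any effect that kept the correlations between genes left over after the diet means. With the preset correlation, a median of 11 of the 42 lists passed (range 3 to 20), and with an estimated correlation none did in any dataset. The p with an estimated correlation therefore stands beside each call.

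The alternatives were quantile normalization applied again, median centring, a fit to the 6 arrays compared, an intensity trend with a robust prior, no moderation, filters on dim probe sets, 1-symbol probe sets alone, array quality weights, other thresholds, camera on ranks, means over the probe sets of a gene, and leaving out each pig in turn. After the array of excess pig 11 was seen to stand apart, further tests of the gene lists without it and a fit with the SD of each array's values as a covariate were added, as was the mixed fry test. Correlations of the differences that share the adequate pigs were compared with 100 simulations of unchanged groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.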

Results

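Whole-transcript arrays gave log2 expression values for 27558 probe sets, covering 12361 named genes, in the longissimus dorsi of 9 finishing pigs. Lysine is an essential amino acid and commonly the first to limit growth in grain-based pig diets. The pigs received a diet deficient, adequate or in excess of lysine for 5 weeks, with 3 pigs in each group, and the comparisons asked how muscle transcripts differed with the lysine supply. In correlation the values of 8 arrays were alike, at 0.977 to 0.992 between them. The array of excess pig 11 stood apart: its correlations with the other arrays ran from 0.904 to 0.956 and the SD of its values was 1.82, against 1.93 to 1.99 on the others. Its bright probe sets lay below those of the other 2 excess pigs, by a median of 0.53 on the log2 scale in the ninth of 10 level bins (a deviation of -0.53), and dim ones lay slightly above. The array quality weights were low for all excess pigs, at 0.19 for pig 10, 0.22 for pig 11 and 0.68 for pig 9, against 0.90 to 2.46 elsewhere. That alternative thus discounts the excess group as a whole.

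**Figure D1:**
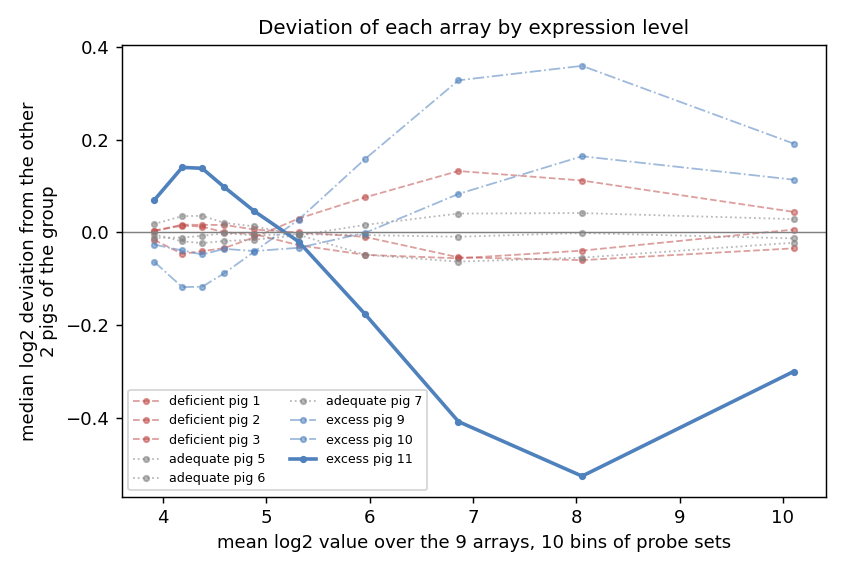
Median log2 deviation of each array from the other 2 pigs of its group (vertical axis) against the mean log2 value over the 9 arrays in 10 bins of probe sets (horizontal axis), 1 line per pig. The line of excess pig 11 falls to -0.53 in the ninth bin, and that pig is part of the reference for the other 2 excess pigs.

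Between lysine-deficient and adequate pigs, PHGDH, PSAT1, PSPH and ATF5, genes of serine synthesis and the amino acid response, passed over their list alone, and none over all probe sets. Here and below, adjustment over a list alone does not correct for the number of lists and comparisons. PHGDH, the first enzyme of the pathway from glycolysis to serine, was 4.46-fold higher (log2 difference 2.16 ± 0.19, SE, n = 3 pigs per group), and PSAT1, the next enzyme, was 4.84-fold higher (2.28 ± 0.50). The level of PHGDH in the adequate pigs, 4.61, lay below the median of all probe sets, 5.07, and no background level was tested, so its fold is not exact. The stress-responsive transcription factor ATF5 was 2.52-fold higher (1.33 ± 0.36) and asparagine synthetase, ASNS, which did not pass over the list, 2.12-fold higher (1.08 ± 0.43). Lower in the deficient pigs were MYL6B, a myosin light chain, by 3.49-fold (log2 difference -1.80 ± 0.42) and CSRP3, a LIM protein of the muscle Z-disc, by 8.32-fold (-3.06 ± 0.74) on one of its probe sets. The log2 difference of CSRP3 was -2.16 without deficient pig 1, whose value of 4.73 lay below the median of all probe sets as well, and -3.85 without deficient pig 2, so this fold is not exact either. The other CSRP3 probe set differed by -1.80 ± 0.78 and the other MYL6B probe set by -1.72 ± 0.42.

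None of the 27558 probe sets passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, and PHGDH had the smallest adjusted p, 0.145. At an unadjusted p below 0.05 there were 511 probe sets, 232 higher and 279 lower, where 0.05 of all probe sets is 1378. That number can be taken as the chance count only if the pooled spread suits these groups. Splits of these 6 arrays that mix the diets gave from 233 to 1121, so the shortfall does not speak for fewer changes than by chance. The count of 511 was 794 without deficient pig 3, 976 without excess pig 11, 941 with only the 6 arrays compared, 1324 with the SD of each array as a covariate and 2207, above 1378, with array quality weights. With these weights PHGDH alone passed (adjusted p = 0.0123, in a range of 0.0123 to 1.00 over its alternatives), while an intensity trend and a test without moderation gave 0 probe sets. The deficient pigs lay fully apart from the adequate pigs for 6.8% of probe sets, against 10% by chance.

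Of the 21 measured amino acid response genes, a list built on the GCN2 and ATF4 pathway, 16 were higher in deficient pigs and 5 lower. PHGDH, PSAT1, PSPH and ATF5 passed when adjusted over the list alone (limma adjusted p = 1.1e-04, 0.021, 0.041 and 0.041), which is 4 genes, against 0 over all probe sets. ASNS and CEBPG passed as well without excess pig 11 (6 genes). PSPH, the last enzyme of serine synthesis, was 1.25-fold higher (0.32 ± 0.09), and the transcript of ATF4 itself differed by 0.05 ± 0.05 (0.081 after quantile normalization was applied again). As a set the list passed camera (adjusted p = 7.53e-08), but not with an estimated correlation (adjusted p = 0.392 with an estimated correlation), and it passed fry for change in either direction (adjusted p = 0.0020). Without PHGDH, PSAT1 and PSPH the mixed fry test called 0 lists in this comparison. The adipocyte markers, among which 10 of 14 were higher with a median of 0.09, lay above the adequate group beside these genes (camera adjusted p = 0.0048, and adjusted p = 0.823 with an estimated correlation). Of them CIDEC, a lipid droplet protein, was 1.48-fold higher and THRSP, a regulator of fat synthesis, 1.98-fold higher (log2 difference 0.98, but 0.63 without deficient pig 2 and 0.64 without adequate pig 7). This list did not pass camera without deficient pig 3 (adjusted p = 0.275) or without adequate pig 7 (adjusted p = 0.139), nor with array quality weights (adjusted p = 0.107).

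Among genes outside that list, FUT1, a fucosyltransferase, was 2.23-fold higher in the deficient pigs (1.16 ± 0.21), RND3, a small GTPase, 1.72-fold higher (0.78 ± 0.15) and EIF2S2, the beta subunit of initiation factor eIF2, 1.44-fold higher (0.52 ± 0.10, on 2 probe sets with identical values). CEP85L, PMS1 and GABPB1 were 1.41-fold, 1.30-fold and 1.22-fold higher, and the other GABPB1 probe set differed by 0.12 ± 0.07. SNX7, a sorting nexin, was 1.41-fold lower and CPEB2, which binds mRNA, 1.35-fold lower. ZNF106, UBTD1, RBM38, PIP4K2A, ZNF181 and ANO10 were lower by between 1.26-fold and 1.52-fold. In all these genes the 3 pigs of one group lay beyond the 3 of the other, and none passed limma's adjusted threshold over all probe sets. In polyamine and creatine metabolism 2 of 10 genes passed over the list alone, both named after their values were seen. ARG2, an arginase, differed by 1.13 ± 0.33 and AMD1, which feeds polyamine synthesis, by 0.45 ± 0.13 (limma adjusted p = 0.049 for both). The median of this list was -0.07 and its mean 0.10, and it did not pass camera (adjusted p = 0.936).

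Of 25 fibroblast and extracellular matrix markers 24 lay below the adequate group, with a median of -0.27, and 9 of them without overlap between the pigs. This list passed camera (adjusted p = 8.28e-13), though not with an estimated correlation (adjusted p = 0.823 with an estimated correlation), and no member passed over the list alone. The excess pigs lay below the same adequate pigs on these markers too, as given below. In the deficient pigs COL1A1, a chain of type I collagen, was 1.37-fold lower (the other probe set differed by -0.27 ± 0.16). FN1, fibronectin, was 1.73-fold lower (log2 difference -0.79, and -0.51 without deficient pig 2). Of 10 fast fibre contractile genes 9 were lower, led by PVALB, the calcium buffer parvalbumin, at 1.43-fold (camera adjusted p = 4.62e-04, and adjusted p = 0.392 with an estimated correlation). The log2 difference of PVALB was -0.52, and -0.31 without deficient pig 1. All 15 immediate early genes were higher, among them NR4A3 by 2.59-fold (camera adjusted p = 5.84e-05, adjusted p = 0.823 with an estimated correlation, and 0.119 by camera without deficient pig 3). Heat shock genes were higher in 20 of 24 cases (adjusted p = 5.84e-05 by camera, adjusted p = 0.823 with an estimated correlation), and DNAJA1, a co-chaperone of HSP70, passed over the list alone at 1.38-fold (limma adjusted p = 0.043), as did CHORDC1 and HSPD1 beside it without excess pig 11 (3 genes).

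Camera called 16 lists in this comparison, 6 higher and 10 lower, but 0 lists with an estimated correlation and 0 by directional fry, where 2 passed at an unadjusted p below 0.05 in each. The other called lists were proteasome subunits and translation factors, which were higher, and glucocorticoid response, glycolysis and glycogen, cholesterol synthesis, cell cycle, smooth muscle and pericyte markers, oxidative phosphorylation, other sarcomere genes and branched-chain amino acid catabolism, which were lower. Their p-values with an estimated correlation ran from an adjusted p = 0.823 to an adjusted p = 0.920, and each of these lists lost its call when at least 1 of the pigs was left out. Myostatin, MSTN, differed by 0.11 ± 0.25, the atrophy ligase FBXO32 by -0.13 ± 0.33 and the lysine-degrading enzyme AASS by -0.12 ± 0.28. Each of these signs turned when 1 of the pigs was left out. SCD, which makes monounsaturated fatty acids, was 2.70-fold higher without overlap between the pigs (1.43 ± 0.42, and 0.95 without adequate pig 7). The fatty acid and triglyceride synthesis list did not pass camera (adjusted p = 0.375).

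**Figure D2:**
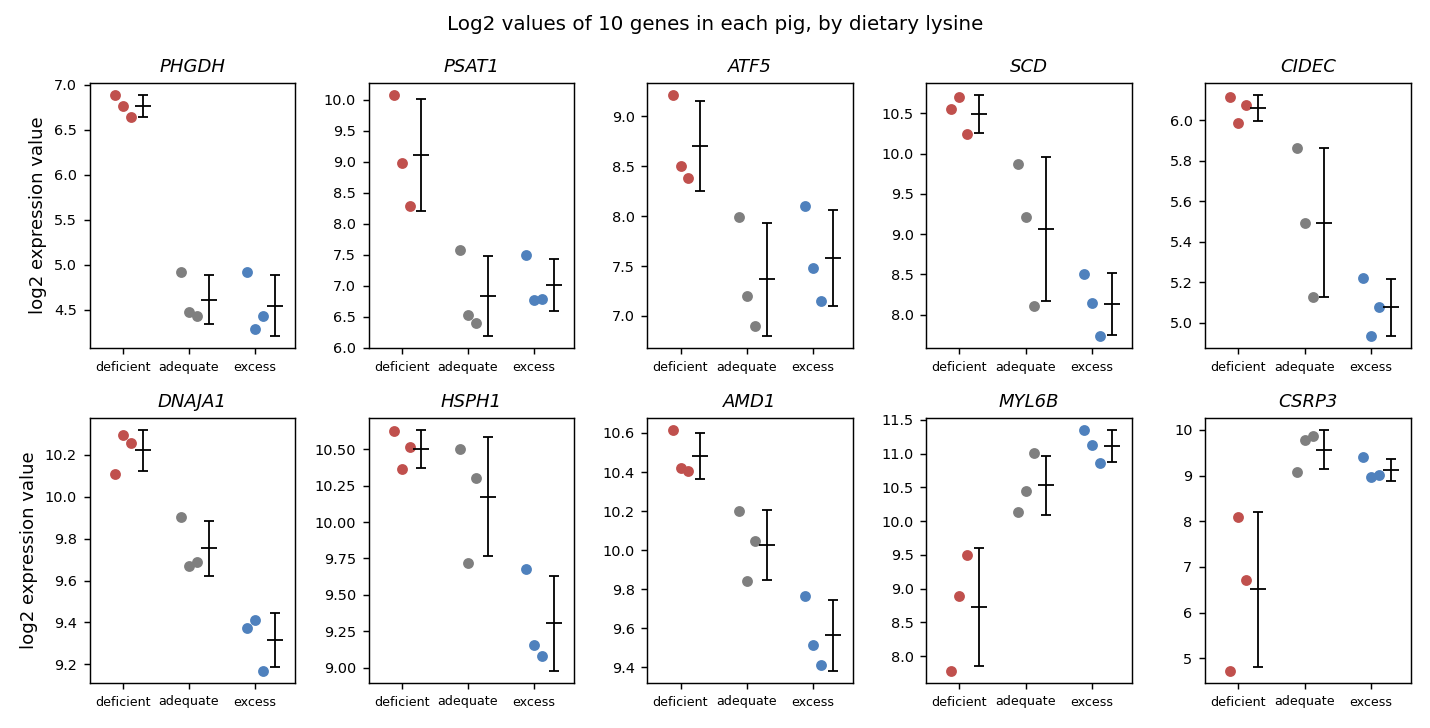
Log2 expression values (vertical axes) of 10 genes in each pig by diet (horizontal axes), with 1 point per pig and the mean ± SD of the 3 pigs as a black bar, on a scale of its own for each gene. The deficient pigs lie above all others for PHGDH, PSAT1 and ATF5, and the group means of SCD, DNAJA1 and AMD1 run down from deficient over adequate to excess.

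Between excess and adequate pigs, 1 slow fibre gene and 3 chaperone genes passed over their list alone, and none over all probe sets. TNNC1, troponin C of slow fibres, was 1.38-fold higher (0.47 ± 0.11, n = 3 pigs per group) and MYL2, a slow myosin light chain, 1.27-fold higher (0.35 ± 0.11). HSPH1, a chaperone of the HSP110 family, was 1.83-fold lower (log2 difference -0.87 ± 0.23), and DNAJA1 and CHORDC1, a co-chaperone of HSP90, were 1.35-fold and 1.40-fold lower. AGT, angiotensinogen, was 2.38-fold lower (-1.25 ± 0.19). PHGDH differed by -0.06 ± 0.19 and PSAT1 by 0.18 ± 0.50, and both signs turned when 1 of the pigs was left out.

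No probe set passed an adjusted p of 0.05 in limma, where the smallest adjusted p was 0.757. At an unadjusted p below 0.05 there were 981 probe sets, 373 higher and 608 lower, a count that changed to 4638 without excess pig 9, to 584 without adequate pig 5, to 589 without adequate pig 6, to 592 with only the 6 arrays compared and to 272 with array quality weights. A test without moderation called 1 probe set, which has no gene symbol here and differed by -0.02, and these weights and an intensity trend called 0. Fully separated were 7% of probe sets, against 10% by chance.

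All 8 measured slow fibre genes were higher, with a median of 0.26 (camera adjusted p = 8.34e-04, adjusted p = 0.636 with an estimated correlation, with 0.0591 by camera without excess pig 9 and 0.213 with array quality weights). CSRP3 counted as higher through its probe set with the highest mean. On its probe set named first above, deficient minus adequate was -3.06 and deficient minus excess -2.61, so excess lay below adequate pigs there. TNNC1 passed over the list alone (limma adjusted p = 0.022), and TPM3 and MYH7, the slow myosin heavy chain, were 1.23-fold and 1.22-fold higher. The log2 difference of MYH7 was 0.16 without excess pig 9 against 0.28 with all pigs. Heat shock genes were lower in 22 of 24 cases with a median of -0.27 (camera adjusted p = 1.43e-06, and adjusted p = 0.636 with an estimated correlation), and DNAJA1, CHORDC1 and HSPH1 passed over the list alone (limma adjusted p = 0.035, 0.035 and 0.046). Without excess pig 11, 0 members of both lists passed over the list alone. All 25 fibroblast and extracellular matrix markers were lower, with a median of -0.29, led by DPT, dermatopontin, at 1.62-fold and MFAP5, a microfibril protein, at 2.05-fold (camera adjusted p = 6.85e-08, and adjusted p = 0.636 with an estimated correlation). The log2 difference of DPT was -0.70, and -0.44 with the SD of each array as a covariate. Between deficient and excess pigs, 16 of the 25 fibroblast and extracellular matrix markers were higher and 9 lower (median 0.05, camera adjusted p = 0.777). Without excess pig 11, 9 were higher and 16 lower (median -0.08, camera adjusted p = 0.521). Both groups thus lay below the same adequate pigs on this list. Both differences may rest on high values in the adequate pigs, which was not tested. In excess against adequate pigs, adipocyte markers were lower in 12 of 14 cases (camera adjusted p = 0.0127, and adjusted p = 0.636 with an estimated correlation). Among them were CFD, the adipose-derived complement factor D, at 1.35-fold and LIPE, hormone-sensitive lipase, at 1.39-fold. This list did not pass camera without adequate pig 5 (adjusted p = 0.052), without excess pig 9 (adjusted p = 0.129), with the dimmest 25 percent of genes left out (adjusted p = 0.0662) or with the covariate (adjusted p = 0.0582). LIPE differed by -0.30 with the covariate against -0.48. Beside them 15 of 17 fatty acid and triglyceride synthesis genes were lower (camera adjusted p = 0.0063, and adjusted p = 0.636 with an estimated correlation), among them SCD at 1.91-fold, DGAT2 at 1.90-fold and ME1, malic enzyme, at 1.39-fold. Their call was lost without excess pig 11, where 5 were higher and 12 lower with a median of -0.12 against -0.27 (camera adjusted p = 0.0661), and with the dimmest 25 percent of genes left out (0.0606) or the covariate (0.5055). The log2 difference of SCD was -0.93, from -0.53 without adequate pig 5 to -1.41 without adequate pig 7.

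Single genes that were lower without overlap between the pigs included LCLAT1, an acyltransferase of cardiolipin remodelling, at 1.59-fold, CLCA2 at 1.78-fold, ERLEC1, an endoplasmic reticulum lectin, at 1.47-fold, ZNF511 at 1.46-fold, CACYBP at 1.37-fold, MFAP3 at 1.26-fold and CFAP20 at 1.24-fold. Higher in the same way were MIR378-1 at 1.53-fold, MALT1 at 1.43-fold on 1 of 2 probe sets (0.51, and 0.34 without adequate pig 7, while the other differed by 0.20 ± 0.11), TMEM178A at 1.40-fold, MIR296 at 1.38-fold, GRIK2 at 1.30-fold and PIP5KL1 at 1.18-fold, besides 2 loci without an approved symbol. Without excess pig 11 the log2 difference of MIR378-1 was 0.34 in place of 0.61, that of MFAP5 was -0.57 in place of -1.04 and that of ME1 was -0.31 in place of -0.48. With the SD of each array as a covariate these were 0.27, -0.50 and -0.27, and TMEM178A differed by 0.29 in place of 0.48. Array quality weights gave -0.66 for MFAP5.

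Camera called 18 lists, 2 higher and 16 lower. Without excess pig 11 it called only 6, 2 higher and 4 lower, and some of these were not among the 18. After quantile normalization was applied again it called 8. With an estimated correlation and by directional fry it was 0 lists, and 1 and 2 lists reached an unadjusted p below 0.05. Besides those above, the lower lists were ribosome biogenesis, autophagy, amino acid sensing, unfolded protein response, the IGF, insulin and mTOR pathway, glucocorticoid response, cytosolic aminoacyl-tRNA synthetases, translation factors, proteasome subunits, calpains, cathepsins and caspases, oxidative phosphorylation, and atrophy ligases with the FOXO axis, while nerve and Schwann cell markers were higher. Their adjusted p ran from an adjusted p = 0.636 to an adjusted p = 0.699 with an estimated correlation. The direction of oxidative phosphorylation flipped after quantile normalization was applied again, and without excess pig 11 proteasome subunits, oxidative phosphorylation and atrophy ligases flipped. The medians without that pig were 0.01 for translation factors and -0.06 for aminoacyl-tRNA synthetases, against -0.13 and -0.28 with it. None of the lists named so far in this paragraph passed camera without it. Of the 6 lists called without that pig, fatty acid oxidation (higher, camera adjusted p = 0.0244) and immediate early genes (lower, 0.0239) were not among the 18.

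Between deficient and excess pigs, some genes of fat synthesis, chaperones and serine synthesis passed over their list alone, and none over all probe sets. SCD was 5.15-fold higher (log2 difference 2.36 ± 0.42, n = 3 pigs per group), DGAT2, which completes triglyceride synthesis, 2.81-fold (1.49 ± 0.34), and ME1, a source of NADPH for fatty acid synthesis, 1.84-fold (0.88 ± 0.15). HSPH1 was 2.30-fold higher, DNAJA1 and CHORDC1 were each 1.87-fold higher (0.90 ± 0.10 and 0.90 ± 0.11), and PHGDH was 4.66-fold higher (2.22 ± 0.19), with a level in excess pigs, 4.54, again below the median of all probe sets. AMD1 was 1.89-fold higher (0.92 ± 0.13). MYL6B was 5.22-fold lower (-2.38 ± 0.42) in the deficient pigs. On the probe set named first above, CSRP3 was 6.12-fold lower (-2.61 ± 0.74, with -1.72 without deficient pig 1 and -3.40 without deficient pig 2).

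None of the probe sets passed limma's adjusted p of 0.05, and PHGDH again had the smallest adjusted p, 0.117 (range 0.0457 to 1.00 over its alternatives). PHGDH alone passed (adjusted p = 0.0457) when only 1-symbol probe sets, or only probe sets at or above the median level, were tested. It met that level only through the deficient pigs, since its means in adequate and excess pigs lay below the median, as given above. A test without moderation called 1 probe set without a gene symbol here, at a difference of 0.02. At an unadjusted p below 0.05 there were 1124 probe sets, 784 higher and 340 lower, where 0.05 of all probe sets is 1378. Here too, 1378 can be taken as the chance count only if the pooled spread suits these groups. The count of 1124 was 3969 without excess pig 9, 1724 with the SD of each array as a covariate, 729 with only the 6 arrays compared and 456 with array quality weights. Of all probe sets 6.5% separated fully against 10% by chance.

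Of 24 heat shock genes 23 were higher in deficient than in excess pigs, with a median of 0.43, and 11 passed when adjusted over the list alone, against 0 over all probe sets. Without excess pig 11 the median was 0.31 and 5 passed over the list alone: HSPA4, HSPH1, DNAJA1, CHORDC1 and HSPD1, the last at a log2 difference of 0.30 against 0.51 with that pig (0.34 with the SD of each array as a covariate). The list passed camera (adjusted p = 3.62e-13), not with an estimated correlation (adjusted p = 0.312 with an estimated correlation), and passed fry for change in either direction (adjusted p = 0.0030). The amino acid response list was higher in 20 of 21 genes, of which PHGDH, PSAT1 and PSPH passed over the list alone, and PHGDH alone without excess pig 11 (camera adjusted p = 2.38e-07, and adjusted p = 0.312 with an estimated correlation; fry in either direction, adjusted p = 0.0030). Its mixed fry call was lost when PHGDH, PSAT1 and PSPH were left out (adjusted p = 0.266).

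Fatty acid and triglyceride synthesis genes were higher in 14 of 17 cases, and SCD, ME1, DGAT2 and THRSP passed over the list alone (camera adjusted p = 0.0013, and adjusted p = 0.565 with an estimated correlation). Without excess pig 11 the median of this list was 0.04 in place of 0.22 and its camera call was lost (adjusted p = 0.0601, and 0.1285 with the SD of each array as a covariate). SCD and ME1 still passed over the list alone without that pig, at log2 differences of 2.17 and 0.72. Of the adipocyte markers, 12 of 14 were higher beside them and 5 passed over the list alone: CFD at 1.60-fold, CIDEC at 1.98-fold, PLIN1, the coat protein of lipid droplets, at 1.84-fold, THRSP at 2.62-fold and LIPE at a log2 difference of 0.57 ± 0.18, and 0.38 without deficient pig 3 (camera adjusted p = 1.75e-05, and adjusted p = 0.565 with an estimated correlation). The adipocyte members past the list-alone threshold without excess pig 11 were CFD and CIDEC. In polyamine and creatine metabolism AMD1 and ARG2 passed over the list alone (limma adjusted p = 0.0011 and 0.0415), and AMD1 alone without excess pig 11.

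All 16 cytosolic aminoacyl-tRNA synthetases were higher in deficient than in excess pigs with a median of 0.36, among them DARS by 0.53 ± 0.17 and GARS by 0.60 ± 0.20, as were 25 of 26 translation factors and 19 of 22 proteasome subunits. These 3 lists passed camera (adjusted p = 1.30e-05, 2.05e-06 and 2.62e-06), and each had an adjusted p = 0.565 with an estimated correlation. Without excess pig 11 their medians were 0.11, 0.04 and 0.10, against 0.36, 0.19 and 0.23 with it. The difference of DARS was 0.32 without that pig. EIF2S2 at 1.54-fold passed over the list of translation factors alone (limma adjusted p = 0.0102). Other genes without overlap between the groups were AGT at 2.18-fold, SERP1 at 1.60-fold and CACYBP at a log2 difference of 0.58 ± 0.09, which were higher in the deficient pigs. ZNF181 at 1.45-fold, BIN1 at 1.37-fold on 1 of 2 probe sets, MYBPC1, a myosin-binding protein of slow fibres, at 1.35-fold, FRZB at 1.34-fold, ZNF106 at 1.33-fold, NDUFA1 at 1.32-fold, GRIK2 at 1.29-fold and CPEB2 at 1.27-fold were lower.

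Camera called 17 lists in this comparison, 15 higher and 2 lower, and 11 without excess pig 11, 7 higher and 4 lower. The 11 include cholesterol synthesis, oxidative phosphorylation and fatty acid oxidation, all lower and not among the 17 (camera adjusted p = 0.0023, 0.0063 and 0.0169). With all pigs, the number of called lists was 0 with an estimated correlation and by directional fry, where 3 lists each reached an unadjusted p below 0.05, and 5 by mixed fry. Immediate early genes, ribosome biogenesis, unfolded protein response, autophagy, amino acid sensing, the IGF, insulin and mTOR pathway, myogenic regulators and ribosomal proteins were the other lists with higher expression, and cell cycle and slow fibre genes, including MYL2 at 1.28-fold, were lower in the deficient pigs. Of these lists only immediate early and slow fibre genes passed without excess pig 11, and slow fibre genes did not pass without excess pig 9 (camera adjusted p = 0.135) or with array quality weights (0.5945). Their p-values with an estimated correlation ran from an adjusted p = 0.565 to an adjusted p = 0.746.

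**Figure D3:**
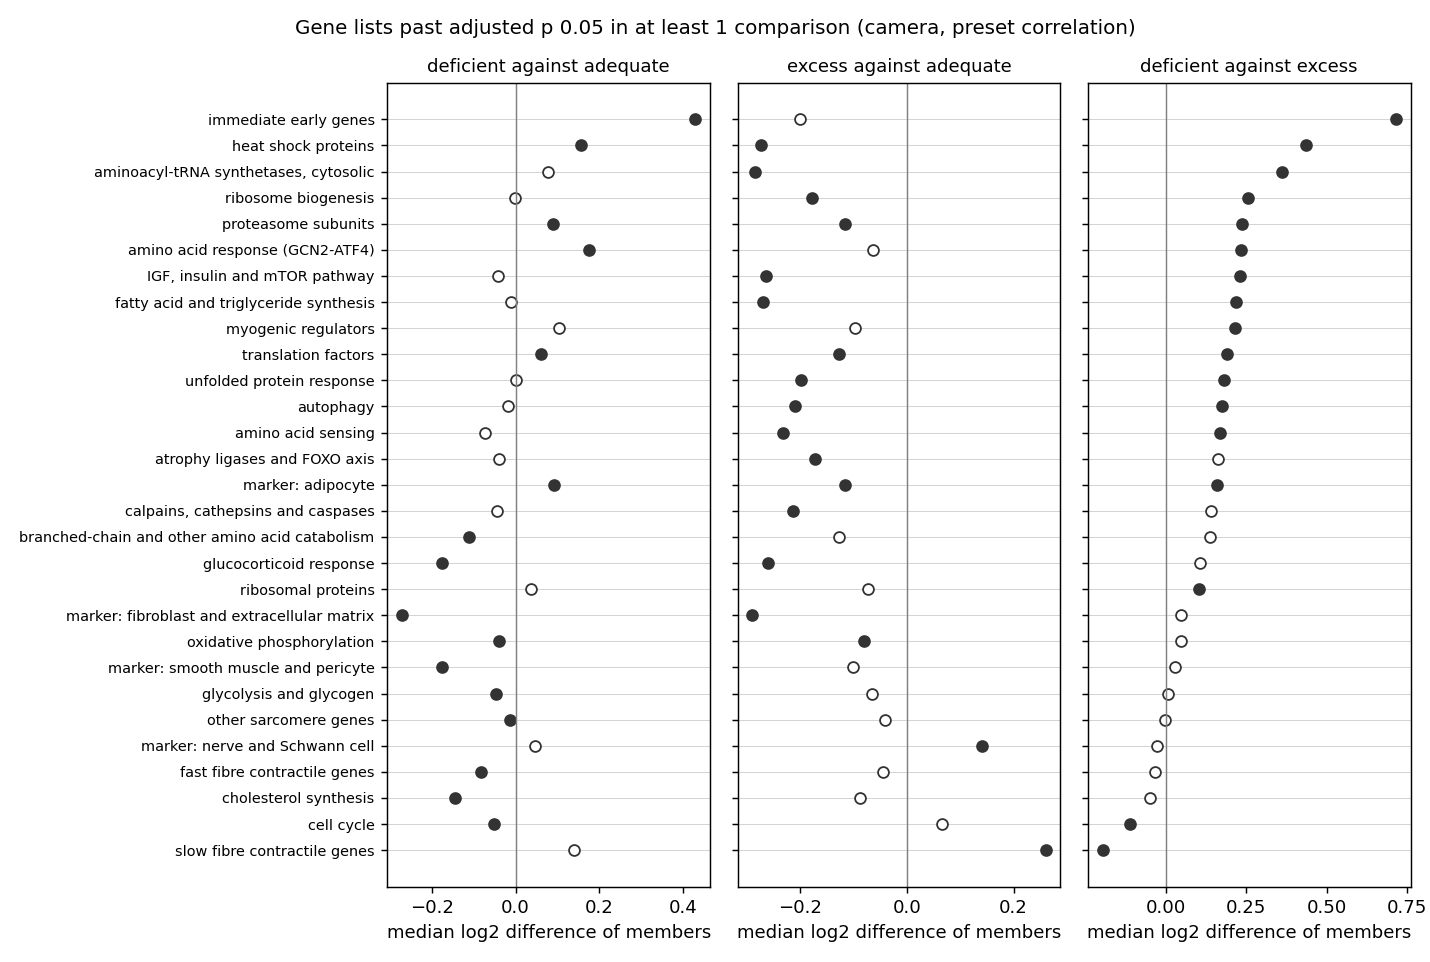
Median log2 difference of the members (horizontal axes) of the 29 gene lists past adjusted p 0.05 in at least 1 comparison (vertical axis), by camera with the preset correlation, in 3 panels for the 3 comparisons. Filled points passed in that comparison and open points did not, and with an estimated correlation 0 lists passed. Heat shock genes lie at 0.16, -0.27 and 0.43 in the panels from left to right.

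Across all 3 diets, limma's F test called 0 probe sets at an adjusted p of 0.05, with 700 at an unadjusted p below 0.05 and a smallest adjusted p of 0.160 for PHGDH, and 0 with an intensity trend and a robust prior. The differences of deficient and of excess pigs from the adequate group correlated across probe sets with a Pearson r of 0.379 and a Spearman rho of 0.393, where genes are not independent replicates. This r was 0.183 without deficient pig 1, 0.0926 without deficient pig 2, and 0.598 both without deficient pig 3 and without adequate pig 7. Unchanged groups simulated against the same adequate arrays gave a mean r of 0.464 with the correlations between genes kept (95% of simulations between -0.36 and 0.964) and 0.502 with independent genes. The covariance was 0.0172 against a simulated 0.0285, and the 2 differences had the same sign for 65.9% of probe sets against 67.2% simulated. All simulated groups had the same spread, whereas the array quality weights were lower for the excess than for the adequate pigs. The simulated values are therefore not an exact reference for no effect. With 3 adequate arrays, separate sets of at least 2 for the 2 differences could not be formed.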

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

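The fits with the SD of each array as a covariate, mixed fry, the combinations that leave out excess pig 11 and the omission of the serine synthesis genes were chosen after the data were seen, and the rest were planned. The count of 0 probe sets past an adjusted p of 0.05 in limma, with 511, 981 and 1124 at an unadjusted p below 0.05, held for each comparison when each pig was left out in turn (0 to 0), where the fit pools the spread of all groups, and so did the 0 of the F test. No moderation gave 1 probe set in excess against adequate and 1 in deficient against excess. Leaving out the dimmest 50 percent, or testing only probe sets with 1 gene symbol, gave 1 in deficient against excess, where fewer tests were adjusted for, and array quality weights gave 1 in deficient against adequate. The probe set called with the dim filter was PHGDH, which that filter kept only through the deficient pigs. An unadjusted p below 0.05 with a 1.2-fold minimum, a looser threshold by construction, gave 345, 723 and 894. The counts of 16, 18 and 17 gene lists ranged from 11 to 18, from 6 to 21 and from 11 to 22 over the pigs left out, with 6 and 11 in the comparisons with excess pigs without excess pig 11. In excess against adequate the count was 8 with quantile normalization applied again, 9 with the dimmest 25 percent of genes left out and 4 with array SD as a covariate, which gave 9 in deficient against excess. With an estimated correlation the counts were 0, 0 and 0, by directional fry 0, 0 and 0, and with an estimated correlation and excess pig 11 left out 0, 0 and 0. Mixed fry gave 1, 0 and 5, then 3, 0 and 5 with excess pig 11 left out, and 0, 0 and 4 with the serine synthesis genes left out of the amino acid response list. The direction of some lists called with all pigs turned, none of them past the threshold there. Lists not called with all pigs were not followed here. In excess against adequate, oxidative phosphorylation turned with quantile normalization applied again (camera adjusted p = 0.805), array quality weights (0.108), without excess pig 11 (0.498), with the covariate (0.858) and with an estimated correlation without that pig (0.932). Proteasome subunits turned with array quality weights (0.934), without excess pig 11 (0.982), with the covariate (0.971) and with an estimated correlation without that pig (0.989). Atrophy ligases turned under the last 3 of these (0.981, 0.549 and 0.989), and translation factors with array quality weights (0.861). With these weights amino acid sensing (0.991) and ribosomal proteins (0.151) turned in deficient against excess, and branched-chain amino acid catabolism turned in deficient against adequate without deficient pig 2 (0.939). Over the pigs left out, the lowest adjusted p of these lists was 1.153e-04 for oxidative phosphorylation, 9.213e-04 for proteasome subunits, 0.0068 for atrophy ligases and 9.444e-04 for branched-chain amino acid catabolism. Genes with differences near 0 changed sign. Over the pigs left out, the deficient minus adequate difference ran from -0.18 to 0.34 for MSTN, from -0.49 to 0.20 for FBXO32 (0.03 without deficient pig 2) and from -0.46 to 0.076 for AASS (0.03 without deficient pig 2 and 0.01 without adequate pig 6). The excess minus adequate difference ran from -0.25 to 0.094 for PHGDH (0.07 without excess pig 10) and from -0.059 to 0.55 for PSAT1 (-0.04 without adequate pig 7), and that of PHGDH was 0.11 with array quality weights and 0.052 with the covariate. Except where the number of tests or a looser threshold is named, the cause was not tested. The correlation of the 2 differences from adequate ran from 0.0926 to 0.598 over the pigs left out. No paired analysis was possible because the pig numbers are not shared between groups.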

Other observations

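The tests of explanations below were chosen after the results were seen, and the splits of the arrays were planned. Lists of lysine catabolism, amino acid transporters and the TCA cycle did not pass camera in any comparison. Of 10 measured lysine catabolism genes, 5 were higher and 5 lower in deficient than in adequate pigs, with a median of -0.01 (adjusted p = 0.669), and the adjusted p was 0.760 for excess against adequate and 0.911 for deficient against excess. Amino acid transporters (19 genes, median 0.05, adjusted p = 0.725), the TCA cycle (17 genes, 0.02, 0.725) and fatty acid oxidation (23 genes, 0.02, 0.725) lay close to 0 in deficient against adequate pigs. Markers of macrophages and myeloid cells had a median of -0.09 (adjusted p = 0.267), and those of lymphocytes 0.00 (0.936), in the same comparison.

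Of 21 amino acid response genes 16 were higher and 5 lower in deficient than in adequate pigs (camera adjusted p = 7.53e-08, adjusted p = 0.392 with an estimated correlation, and 0.846 by mixed fry without PHGDH, PSAT1 and PSPH). The 4 genes past the list-alone threshold, picked in this same comparison, had a mean log2 difference of 1.52 ± 0.289 (SE). With the SD of each array as a covariate it was 1.54 ± 0.304. The array SDs ran from 1.94 to 1.99 in deficient and from 1.95 to 1.98 in adequate pigs, and excess pig 11, at 1.82, lay furthest off. The covariate could therefore hardly move this difference, and the fit does not decide whether the spread of values was a cause. The 8 adipocyte markers at or above the median level had a median difference of 0.205 (SD 0.349). It was set against the mean of those 4 genes, which may be too high because they were picked for passing in this comparison. The part of adipocyte RNA was therefore not settled. A response of muscle to low lysine is a candidate explanation, found and tested on the same data, and other differences between the pigs stay open.

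The array of excess pig 11 stood apart from the other 8. The rank correlation of level and deviation from the other 2 pigs of its group was -0.541, outside the range of -0.202 to 0.456 on the other arrays, but this restates the lower SD of that array and decides nothing, so signal compressed with level stays open as a cause. Its highest rank correlation with another array was 0.936, below the lowest among the other 8, 0.950, which argues against a change of distribution alone. Of 8 cell type marker lists the highest, endothelium, lay at percentile 86.0 of 10000 random lists, and a small share of another cell type stays open. No other biological explanation was tested.

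Most heat shock and fat synthesis genes, 23 of 24 and 14 of 17, lay higher in deficient than in excess pigs, but between deficient and adequate pigs the fat synthesis list went both ways, with a median of -0.01 (adjusted p = 0.375), 3 of 17 genes higher at an unadjusted p below 0.05 and SCD higher by 1.43. Without excess pig 11 the heat shock median, deficient minus excess, was 0.308 against 0.434 with it, and 21 of 24 genes were higher, which argues against that array as the whole cause. For fat synthesis genes the median was 0.043 against 0.218, with 10 of 17 higher. This fall is what that array as a cause predicts, and the median of the list depended on that array. With only 10 of 17 genes still higher the test was counted as undecided, so that array as a cause stays open. SCD and ME1 still passed over that list alone without it. Of 7 adipocyte markers outside that list and at or above the median level, 4 passed over the list alone in the same direction, and without excess pig 11 only 2, CFD and CIDEC, so a part of adipocyte RNA in the fat synthesis difference stays open. A response to the diet stays open as untested.

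For each pair of diets the 6 arrays make 10 splits, too few for a share under 0.05. For probe sets past the adjusted threshold the real counts were 0, 0 and 0 and the highest others 0, 1 and 2; every split reaches a count of 0 (10, 10 and 10 splits), so this says nothing about chance. At an unadjusted p below 0.05 the real counts were 511, 981 and 1124, reached in 4, 4 and 4 splits, and the highest others 1121, 4492 and 4291. For gene lists the real counts were 16, 18 and 17, reached in 1, 2 and 3 splits, and the highest others 13, 19 and 21. The same holds across all diets for the real 0 of the F test (100 of 100 drawn splits, highest other 3). At an unadjusted p below 0.05, 41 of the 100 splits gave at least the real 700 of the F test (highest other 3844), so chance cannot be excluded for that count. Some splits that mix the diets gave larger counts than the real one: 4492 came from joining excess pig 9 with adequate pigs 5 and 6, against adequate pig 7 and excess pigs 10 and 11. This split also sorted the 6 arrays by the SD of their values. The SD was 1.98 for pigs 5, 6 and 9, and 1.95, 1.93 and 1.82 for pigs 7, 10 and 11. The cause of the larger counts was not tested.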
